A study of Homo sapiens with 15 samples.

How the data were processed

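The series measured mRNA levels in C2-M cells, a cultured model of intestinal M cells, the epithelial cells that take up particles and microbes over lymphoid follicles. C2BBe1, a subclone of the human colon carcinoma line Caco-2 that forms a brush border, was the parent line. Per the labels' protocols, C2BBe1 cells grew for 21 days on Transwell filters and then for 72 hours with Raji cells, a human B cell line. The series' own design text instead places the Raji cells in the culture during the 21 days, and which of the 2 schedules was used is not given in the sources used here. The cultures were then left alone or incubated for 2 hours with Lactobacillus salivarius, Escherichia coli, Bacteroides fragilis or polystyrene beads. There were 5 groups of 3 arrays, which gave 15 arrays in all, and the titles call the arrays of a group biological replicates. How the cultures of a group were made, the bacterial dose and the bead dose are not given in the sources used here.

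Per the labels' protocols, total RNA was extracted with the mirVana method, 1 ug of it was amplified in a single round and biotin-labelled with an Enzo kit, and the product was hybridised to Affymetrix arrays. The deposited values are MAS5 signal intensities, 1 per probe set and array, per the submitters' processing notes. The MAS5 version, the scaling target and any detection calls are not given in the sources used here. The deposited intensities were positive, on a linear scale and already scaled, since the mean of every array after removing 2% of probe sets at each end came to 250. The array median lay between 37.0 and 45.8 intensity units. An array has no read depth. The number of arrays per group limits the precision.

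From these intensities, log2(signal + 1) was computed and no further normalisation was applied. The table held 54675 probe sets, of which 62 were control probe sets that were left out of the tests and used to compare the arrays. A probe set was tested if its signal reached the array's own median on at least 3 of the 15 arrays, which left 30192. Gene names came from the platform annotation supplied with the series: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Symbols were looked up by Entrez gene identifier in a table of human genes on assembly GRCh38.p14. No symbol changed, and 54 identifiers were absent from that table and kept their annotated symbol. No coordinates are given, because the deposited values carry no genome build. One probe set stood for each gene, namely that with the highest mean log2 signal among the gene's probe sets with a single symbol, with cross-hybridising types (suffix _x_at) used where there was no other. This gave 12996 genes tested.

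All 15 arrays entered 1 linear model per probe set in limma 3.58.1 under R 4.3.3, with a mean for each group and eBayes with an intensity trend, so that all groups shared their estimate of spread (10 residual degrees of freedom, median prior degrees of freedom 7.64). The 10 pairwise differences, the mean of the 3 bacterial groups against the mean of the control and bead groups, and a moderated F test over all groups were taken from that model. P values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p below 0.05 was called a change. All tests were two-sided. Values after ± are standard errors of the limma model with n = 3 arrays per group, and differences are on the log2 scale unless a fold is named.

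Before the data were examined, 21 gene lists were fixed with 615 genes, of which 492 were tested. They covered immediate early genes, NF-kB targets with chemokines and cytokines, interferon-response genes, microbe-sensing receptors, M cell markers, enterocyte genes, junction proteins, uptake machinery, antimicrobial and mucin genes, heat shock genes, the unfolded protein response, hypoxia and glycolysis, NRF2 targets, metallothioneins and zinc carriers, cholesterol synthesis, xenobiotic metabolism, cell cycle genes, apoptosis and p53 targets, EGF receptor ligands with their feedback genes, B cell genes, and goblet and enteroendocrine genes. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within each comparison. Camera asks whether a list's genes differ more than the other genes do. Camera with an estimated correlation and fry were the alternatives. For each list the members past the threshold are counted among all probe sets tested, and also with p adjusted over the list alone. Of the 21 B cell genes tested, 11 reached the median level in control arrays, so part of that list is also expressed by, or carried into, the control cultures.

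The rule for named genes, also fixed before the data were examined, took up to 10 genes with the largest rise and up to 10 with the largest fall in each comparison with the control and in the comparison of the 3 bacteria, among genes past the threshold whose arrays did not overlap. Where fewer than 5 genes qualified on a side, genes with the smallest p were to be added up to 5. In the other comparisons it took up to 5 each way. It added up to 4 members of each list that passed, and EGR1, FOS, CXCL8, CCL20, NFKBIA, TNFAIP3, TLR2, TLR4, GP2 and SPIB in each comparison with the control. TLR4 and GP2 did not pass the level filter and were not tested. Y-linked genes were left out. The choice of 5 lists for close reporting (NF-kB, immediate early, hypoxia and glycolysis, cell cycle, enterocyte) was made after the results were seen.

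The alternatives fixed beforehand were no level filter (54613 probe sets), a stricter filter at the 75th percentile (14901), a pseudocount of 16, quantile normalisation, median centring, eBayes without the trend, a model of only the arrays compared, the replicate number as a block, and leaving out each array in turn. A model without the bead arrays (12 arrays) and the comparison of the 3 bacteria with the control alone were added after the data were seen. The procedure was tested on simulated arrays built from each probe set's mean over all 15 arrays and its spread in the 5-group model. On the simulated E. coli arrays, 200 of 30192 probe sets were changed in each of 10 draws. Against the simulated controls, the procedure recovered 30.9% of changes of 0.5 log2, 70.0% of changes of 1 and 93.2% of changes of 2. Of its calls, 5.27% were false. The real E. coli comparison with the control gave 2706 calls, so these shares need not hold there. A list shifted by 0.5 was called in 20 of 20 simulated data sets with 12996 genes. No list was called in an unchanged comparison within the same sets. These sets were built from means and spreads without correlation between genes. They therefore cannot show whether the preset correlation of camera is adequate for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.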

Results

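The arrays measured gene expression in C2-M cells left alone (control) or kept for 2 hours with Lactobacillus salivarius, Escherichia coli, Bacteroides fragilis or polystyrene beads, with 3 arrays in each of the 5 groups. C2-M cells are Caco-2-type epithelial cells (C2BBe1) turned towards an M cell character by culture with Raji B cells. The design asks how such cells respond to each of 3 commensal bacteria, and the beads provide a particle without bacterial products. Array medians lay between 37.0 and 45.8 intensity units. Pearson correlations of log2 signal across probe sets ran from 0.971 to 0.981 within groups and from 0.952 to 0.980 between groups (genes are not independent replicates). Of the 30192 probe sets tested, 9027 differed between groups in the moderated F test of limma.

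The bead arrays stood apart from the other 12 in control probe sets that do not come from the cells' mRNA. Their hybridisation controls averaged 11.10 to 11.32 log2 units per array, against 10.48 to 10.79 on the other arrays, and their added poly-A controls 9.75 to 9.92, against 8.94 to 9.26 on control arrays. Signals for 18S ribosomal RNA were 860 to 1695 on bead arrays and 6961 to 9460 elsewhere. The ratio of 3' to 5' signal for actin (ACTB) was 1.90 to 2.07 with beads, 1.38 to 1.62 in controls, 1.55 to 1.70 with L. salivarius, 1.42 to 1.49 with E. coli and 1.74 to 1.84 with B. fragilis. Poly-A controls were lower than on every control array with E. coli (8.44 to 8.56), B. fragilis (8.27 to 8.59) and L. salivarius 1 and 2 (8.64 and 8.55, against 9.38 for L. salivarius 3), and hybridisation controls lower with B. fragilis, so a difference in RNA amount or labelling may enter the comparisons of bacteria with the control and is not separated from them. All bead arrays share the features of their group, so a separate round of labelling or hybridisation and the bead treatment cannot be told apart in any comparison with beads.

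**Figure D1:**
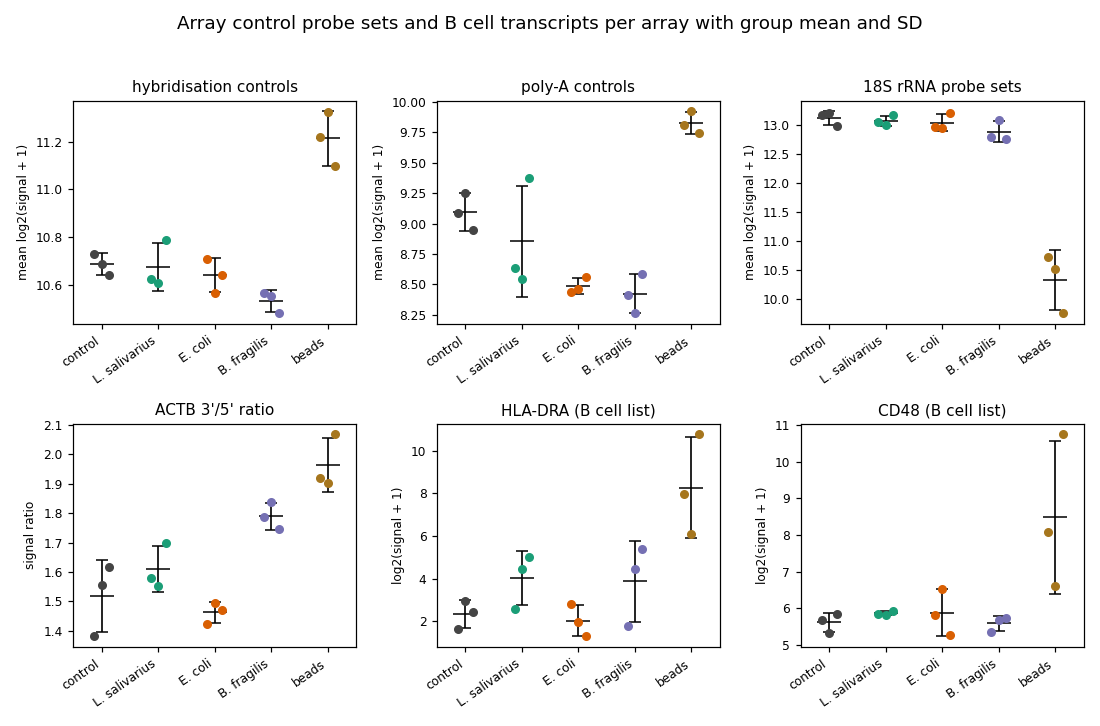
Control probe sets and 2 B cell transcripts on each array. The vertical axes give mean log2(signal + 1), or the signal ratio for ACTB; points are arrays, bars the group mean and SD of 3 arrays. Bead arrays lie above all others for hybridisation controls and below all others for 18S ribosomal RNA, and their HLA-DRA values spread from 6.10 to 10.78.

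After 2 hours with E. coli, the C2-M cells carried far more mRNA for neutrophil- and T cell-attracting chemokines and for feedback inhibitors of NF-kB. CXCL3 rose by 3.18 ± 0.27 (9.09-fold, adjusted p = 4.03e-06), CXCL1 by 2.76 ± 0.27 (6.75-fold, adjusted p = 1.46e-05) and CXCL10, an interferon-inducible chemokine, by 2.13 ± 0.31. Control arrays were weak for CXCL10 (4.22 to 5.42), so the size of its rise is less certain. CXCL8, which encodes interleukin-8, rose by 4.11 ± 0.68 (17.3-fold, adjusted p = 0.00135) from a control mean of 3.52, which lies below the array medians of 5.25 to 5.55, so the size of its fold depends on a weak baseline. Its other probe set, of the cross-hybridising type and with a control mean of 5.05, rose by 4.54 ± 0.37 (limma adjusted p = 2.36e-06). The inhibitors TNFAIP3 (A20) and NFKBIA rose by 1.84 ± 0.14 and 0.97 ± 0.11. NFKBIZ, also of the NF-kB group, rose by 1.97 ± 0.12. PTGS2, the inducible cyclooxygenase, rose by 1.93 ± 0.29, and CCL20, which attracts dendritic and B cells, by 1.04 ± 0.16.

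Of 30 NF-kB and cytokine genes tested, 13 rose and 2 fell with E. coli (15 and 2 adjusted over the list alone; camera adjusted p = 2.94e-08, and adjusted p = 0.183 with an estimated correlation). Immediate early genes, the transcription factors and regulators induced within minutes of a stimulus, moved the same way: 15 of 35 rose and 1 fell (17 and 2 over the list alone; camera adjusted p = 4.1e-08, and adjusted p = 0.183 with an estimated correlation). CCN1 rose by 1.31 ± 0.12, FOS by 1.05 ± 0.10 and JUN by 0.89. EGR1 rose by 0.62 ± 0.15 (adjusted p = 0.0164), and without control 2 its adjusted p was 0.068. Hypoxia-type genes included 8 of 33 that rose and none that fell (10 and 0 over the list alone; camera adjusted p = 0.000798, and adjusted p = 0.269 with an estimated correlation), with ANKRD37 up by 1.27 ± 0.11, HILPDA by 0.94 and the vasoactive peptide ADM by 0.76.

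Among 33 cell cycle genes, 13 rose and none fell with E. coli, and 23 rose over the list alone (camera adjusted p = 3.54e-09, and adjusted p = 0.269 with an estimated correlation). CCNA2, the S phase cyclin, rose by 0.63. Enterocyte genes went the other way as a list, with 1 of 32 up and 2 down (the same counts over the list alone; camera adjusted p = 0.000606, and adjusted p = 0.269 with an estimated correlation). KRT20, a keratin of differentiated gut epithelium, fell by 1.19 ± 0.21. Heat shock genes (0 up, 3 down of 20, or 1 and 4 over the list alone; camera adjusted p = 0.00667, and adjusted p = 0.269 with an estimated correlation) and cholesterol synthesis genes (0 up, 2 down of 19, the same over the list alone; camera adjusted p = 0.00667, and adjusted p = 0.269 with an estimated correlation) also stood below the other genes. The unfolded protein response (0 up, 3 down of 25; adjusted p = 0.0612), interferon-response (4 up, 0 down of 28; adjusted p = 0.0916) and NRF2 lists (0 up, 3 down of 26; adjusted p = 0.0612) did not pass. Neither did the M cell list (1 up, 1 down of 16) or the B cell list, where none of 21 passed and the median difference was -0.21. TLR2 (0.31) and SPIB (-0.34), a transcription factor of M cells, did not pass either.

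In total, 963 probe sets were higher and 1743 lower with E. coli than in controls, 77 and 384 of them by at least 2-fold. By chance 10% of probe sets have arrays that do not overlap, and 28.5% did. The direction of the count depends on the scaling: median centring, which moved the median of all probe sets by 0.0977, gave 1519 higher and 1046 lower. Among the largest falls were ZNF324 (-2.70 ± 0.45) and SUZ12P1 (-2.05 ± 0.35), and 30.8% of the probe sets that fell carry no gene symbol, against 14.4% of those tested. Without control 1 the total was 1195, without control 3 it was 1559 and without E. coli 2 it was 1445, against 2706 with all arrays. Of 72 named genes past the threshold, 43 kept their call whichever array was left out.

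**Figure D2:**
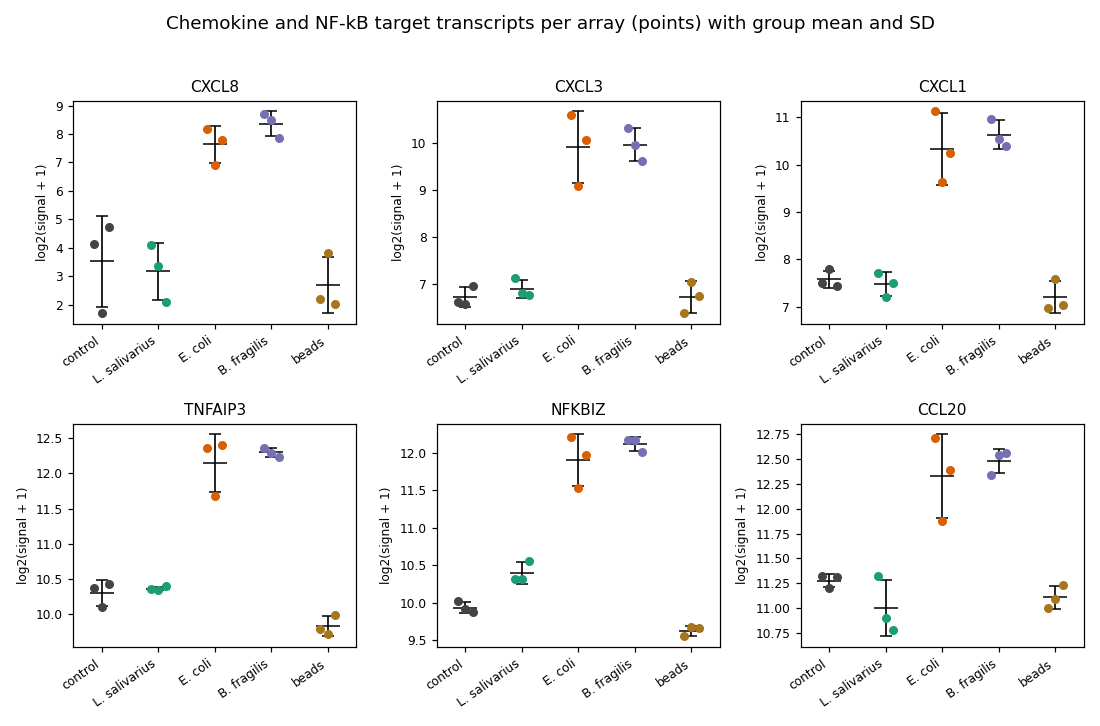
6 transcripts of the chemokine and NF-kB group on each array. The vertical axes give log2(signal + 1); points are arrays, bars the group mean and SD of 3 arrays. E. coli and B. fragilis arrays lie above those of the other groups in each panel, by 4.11 and 4.84 over the control mean for CXCL8 and by 1.84 and 2.00 for TNFAIP3.

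B. fragilis gave the largest number of changed probe sets of the 3 bacteria, and chemokine mRNA rose again. CXCL8 rose by 4.84 ± 0.68 (28.6-fold, adjusted p = 0.000291), CXCL3 by 3.23 ± 0.27 (9.38-fold), CXCL1 by 3.06 ± 0.27 (8.33-fold) and CXCL10 by 2.53 (5.76-fold). NFKBIZ rose by 2.19 ± 0.12 (4.55-fold, adjusted p = 2.74e-08), PTGS2 by 2.22 (4.65-fold), TNFAIP3 by 2.00 ± 0.14 and the cytokine IL6 by 2.02 ± 0.38. CCL20 rose by 1.20 and NFKBIA by 1.12. The CXCL8 fold again rests on a control mean of 3.52. Control arrays were also weak for CXCL10 (4.22 to 5.42) and IL6 (4.10 to 4.93), so the sizes of their rises are less certain. The other CXCL8 probe set, with a control mean of 5.05, rose by 5.26 ± 0.37. FKBP10, a collagen chaperone, rose by 3.16 ± 0.67 from a weak control mean of 4.12; with E. coli it rose by 2.69, which was lost without control 1 (adjusted p = 0.106), E. coli 2 (0.0642) or E. coli 3 (0.0590).

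With B. fragilis, 14 of 30 NF-kB and cytokine genes rose and 2 fell (16 and 2 over the list alone; camera adjusted p = 3.81e-08, and adjusted p = 0.174 with an estimated correlation), and 17 of 35 immediate early genes rose and 2 fell (20 and 2 over the list alone; camera adjusted p = 4.21e-08, and adjusted p = 0.174 with an estimated correlation). FOS rose by 1.09 ± 0.10 and EGR1 by 0.76 ± 0.15. Interferon-response genes rose as a list, 6 of 28 with none down (10 and 3 over the list alone; camera adjusted p = 0.0261, and adjusted p = 0.174 with an estimated correlation), among them IFIT2 by 1.05 and IFIT3 by 0.73. Of the xenobiotic genes, 3 of 13 rose and 1 fell (list adjusted p = 0.727), and the targets of the aryl hydrocarbon receptor CYP1A1 and TIPARP rose by 0.95 ± 0.20 (adjusted p = 0.0048) and 0.86. Hypoxia-type genes included 8 of 33 up and 1 down (9 and 1 over the list alone; camera adjusted p = 0.00269, and adjusted p = 0.290 with an estimated correlation).

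Cell cycle genes rose here too, 13 of 33 with none down (26 over the list alone; camera adjusted p = 1.83e-10, and adjusted p = 0.253 with an estimated correlation). Of 32 enterocyte genes, 9 fell and 1 rose (12 and 1 over the list alone; camera adjusted p = 6.44e-06, and adjusted p = 0.174 with an estimated correlation). KRT20 fell by 1.35 ± 0.21, and the 1 that rose was CDX2, the intestinal transcription factor, by 0.49. MTTP, which loads lipid onto apolipoprotein B, fell by 1.21, but its adjusted p was 0.0753 without control 1, 0.0605 without control 3 and 0.0821 without B. fragilis 2. Cholesterol synthesis (0 up, 2 down of 19, the same over the list alone; camera adjusted p = 0.00208, and adjusted p = 0.174 with an estimated correlation), the unfolded protein response (0 up, 3 down of 25, the same over the list alone; camera adjusted p = 0.036, and adjusted p = 0.325 with an estimated correlation) and heat shock genes (0 up, 2 down of 20, or 1 and 5 over the list alone; camera adjusted p = 0.0424, and adjusted p = 0.299 with an estimated correlation) lay below the other genes. The remaining lists did not pass as lists; their largest counts were 5 up and 2 down of 21 for antimicrobial and mucin genes and 4 up and 3 down of 21 for EGF receptor ligands and feedback genes. None of the 21 B cell genes rose and 1 fell, and SPIB (-0.23) and TLR2 (-0.14, or 0.04 after median centring) did not pass.

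In total, 1452 probe sets were higher and 2420 lower with B. fragilis than in controls, 112 and 691 of them by at least 2-fold, and 32.9% had arrays that did not overlap (10% by chance). Median centring, which moved the median of all probe sets by 0.175, gave 4415 higher and 1426 lower, so the balance of rises and falls turned with the scaling. The falls again held many probe sets without a gene symbol (31.9%), and the ACTB 3'/5' ratio of these arrays lay above that of the controls. Without control 1 the total was 1842 and without control 3 it was 2317, against 3872. Of 80 named genes past the threshold, 51 kept their call whichever array was left out.

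L. salivarius changed fewer genes, and no chemokine or NF-kB gene was among them. The genes that rose in every model were ANKRD37, a hypoxia-inducible ankyrin repeat protein, by 1.15 ± 0.11 (2.22-fold, adjusted p = 0.000133), HILPDA, a lipid droplet protein also induced by hypoxia, by 0.79 ± 0.09 (adjusted p = 0.000506), the matricellular protein CCN1 by 0.98 ± 0.12 (adjusted p = 0.000839), RNF186, a ubiquitin ligase of colon epithelium, by 1.08 ± 0.15 (adjusted p = 0.00364) and ZBTB24 by 0.97 ± 0.14 (adjusted p = 0.00527). ZSWIM3 fell by 1.21 ± 0.19 (adjusted p = 0.00678) and SQSTM1, the autophagy receptor p62, by 0.54, a fall that none of its 4 other probe sets shared. These 7 were the named genes that kept their call whichever array was left out, of 32 past the threshold. CXCL8 (-0.34 ± 0.68, adjusted p = 0.862), CCL20 (-0.28), NFKBIA (-0.14), TNFAIP3 (0.06), EGR1 (0.38, though another of its probe sets passed at 0.51, adjusted p = 0.0343), TLR2 (-0.15) and SPIB (-0.19) did not pass. Signs of the small differences in CXCL8, TNFAIP3 and SPIB turned when single arrays were left out: CXCL8 was 0.26 without control 3 and 0.20 without L. salivarius 3, and without control 2 TNFAIP3 was -0.04 and SPIB 0.02.

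None of the 30 NF-kB and cytokine genes passed with L. salivarius (3 rose over the list alone; camera adjusted p = 0.907). Of 33 hypoxia-type genes, 4 rose and none fell (7 and 0 over the list alone; camera adjusted p = 5.01e-06, and adjusted p = 0.175 with an estimated correlation). The 33 cell cycle genes stood above the other genes as a list (camera adjusted p = 1.63e-06, and adjusted p = 0.434 with an estimated correlation), though none passed alone and 11 rose over the list alone. Immediate early genes were mixed and did not pass as a list (camera adjusted p = 0.378 for the list). Of 35, 4 were up, CCN1 and FOS included, and 2 down, MYC among them. FOS rose by 0.48 (adjusted p = 0.0328), which was lost without control 1 (0.147), control 3 (0.126), L. salivarius 1 (0.0709), L. salivarius 2 (0.111) and L. salivarius 3; MYC fell by 0.42, which was lost without any of those arrays or control 2 (0.0642). KRT20 fell by 1.09 ± 0.21 (adjusted p = 0.0202), with adjusted p of 0.0841 and 0.0938 without control 1 or 3 and 0.0689 and 0.0891 without L. salivarius 2 or 3. Enterocyte genes as a list did not pass (1 up, 1 down of 32; adjusted p = 0.0883). Heat shock genes (0 up, 1 down of 20, the same over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.175 with an estimated correlation) and the unfolded protein response (0 up, 1 down of 25, or 0 and 4 over the list alone; camera adjusted p = 0.00437, and adjusted p = 0.286 with an estimated correlation) lay below the other genes. No member passed among the microbe-sensing, M cell, junction, uptake, metallothionein, cholesterol, xenobiotic, EGF receptor and B cell lists, and the median of the B cell list was 0.30.

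In total, 96 probe sets were higher and 199 lower with L. salivarius than in controls, 7 and 46 of them by at least 2-fold, and 22.5% had arrays that did not overlap (10% by chance). Median centring gave 44 higher and 180 lower. This count is the least stable of the comparisons with the control: it was 35 without control 1, 63 without control 3, 70 without L. salivarius 1, 119 without L. salivarius 2 and 92 without L. salivarius 3, against 295 with all arrays.

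The calls for the 3 bacteria overlapped. Rises shared by E. coli and B. fragilis numbered 679 (46.3 expected from independent lists) and shared falls 1313 (140 expected), with no probe set moving in opposite directions. L. salivarius shared 83 rises and 180 falls with E. coli (3.06 and 11.5 expected), and their log2 differences correlated at 0.687, above the simulated value, with a covariance 0.0610 above the simulated one. The log2 differences of E. coli and B. fragilis correlated at 0.798 across probe sets, against 0.501 in 100 simulations of unchanged groups with shared controls, and their covariance exceeded the simulated one by 0.107. Part of the excess in shared calls may come from the shared control arrays, since 3 arrays are too few to be split. B. fragilis and beads shared 990 falls (299 expected); their correlation of 0.439 lay below the simulated value and their covariance 0.0548 above it, so these measures do not settle whether they share a change.

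A direct comparison of the bacteria shows where the chemokine response differed. With E. coli, CXCL3 was higher than with L. salivarius by 3.01 ± 0.27, CXCL1 by 2.85 ± 0.27, TNFAIP3 by 1.78 ± 0.14, NFKBIZ by 1.51 ± 0.12, and CCL20 by 1.32 ± 0.16 (adjusted p = 0.000290 for CCL20 and lower for the others). With B. fragilis these genes were higher than with L. salivarius by 3.05 (CXCL3), 3.16 (CXCL1), 1.93 (TNFAIP3), 1.72 (NFKBIZ) and 1.48 (CCL20), and NFKBIA was higher by 1.27. CXCL8 was higher by 4.45 ± 0.68 with E. coli (adjusted p = 0.00652, but 0.052 without E. coli 1 and 0.0569 without E. coli 3) and by 5.18 with B. fragilis. On its other probe set it was higher by 4.10 ± 0.37 (limma adjusted p = 1.1e-05) and 4.82 ± 0.37 (limma adjusted p = 8.85e-07). CYP1A1 was higher with B. fragilis than with L. salivarius by 1.51 and TIPARP by 0.78.

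Of 30 NF-kB and cytokine genes, 8 were higher and none lower with E. coli than with L. salivarius (11 and 1 over the list alone; camera adjusted p = 5.93e-19, and adjusted p = 0.0128 with an estimated correlation), and 9 higher and 1 lower with B. fragilis (13 and 1 over the list alone; camera adjusted p = 3e-14, and adjusted p = 0.0353 with an estimated correlation). Immediate early genes counted 7 higher with E. coli and 8 with B. fragilis of 35, with none lower (15 and 0, and 19 and 2, over the list alone; adjusted p = 0.0220 and 0.0470 with an estimated correlation). In all, 43 probe sets were higher and 2 lower with E. coli than with L. salivarius, and 70 higher and 80 lower with B. fragilis (median centring: 57 and 2, and 312 and 46, after median shifts of 0.104 and 0.181). Without L. salivarius 1 or 2 or E. coli 3, the E. coli total of 45 became 29, 26 and 20. The B. fragilis total of 150 became 72, 39 and 63 without L. salivarius 1, 2 or 3, and 82, 64 and 79 without B. fragilis 1, 2 or 3.

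E. coli and B. fragilis did not differ in any probe set in the limma test at the adjusted threshold (smallest adjusted p = 0.554). An unadjusted limma p below 0.05 was found for 1561 of 30192 probe sets, close to the share given by chance. Arrays did not overlap for 10.7% (10% by chance). Without E. coli 1, 1 probe set passed the adjusted threshold. CXCL8 differed by -0.73 ± 0.68, CXCL3 by -0.04, TNFAIP3 by -0.15 and CYP1A1 by -0.88 (adjusted p = 0.554), as E. coli minus B. fragilis. The adjusted p values do not show that the responses were alike.

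Cells kept with beads had lower immediate early mRNA than controls, with the arrays set apart as described. FOSB fell by 3.27 ± 0.26, the transcription factor KLF2 by 2.50 ± 0.27, the phosphatase DUSP1 by 1.71 ± 0.09 (adjusted p = 4.03e-09), ZFP36, which destabilises cytokine mRNA, by 1.64, FOS by 1.59 ± 0.10 and ATF3 by 1.34. Of 35 immediate early genes, 27 fell and 1 rose (the same over the list alone; camera adjusted p = 1.01e-16, and adjusted p = 0.0365 with an estimated correlation), with a median of -0.53. EGR1 differed between its probe sets and the one that stands for it did not pass (-0.29). CYP4F12, a fatty acid hydroxylase, fell by 3.40 ± 0.25.

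The beads also lay below controls in EGF receptor ligands and feedback genes (0 up, 9 down of 21, the same over the list alone; camera adjusted p = 0.000205, and adjusted p = 0.0584 with an estimated correlation), such as EREG (-1.13), in the unfolded protein response (0 up, 9 down of 25, the same over the list alone; camera adjusted p = 0.000422, and adjusted p = 0.108 with an estimated correlation), such as PPP1R15A (-1.24) and DDIT4 (-1.11), in cholesterol synthesis (2 up, 11 down of 19, or 2 and 14 over the list alone; camera adjusted p = 0.000575, and adjusted p = 0.108 with an estimated correlation), such as INSIG1 (-0.84) and SQLE (-0.68), and in xenobiotic genes (1 up, 5 down of 13, the same over the list alone; camera adjusted p = 0.0355, and adjusted p = 0.108 with an estimated correlation). NF-kB genes fell in 9 of 30 and rose in 1 (10 and 1 over the list alone; adjusted p = 0.0509); NFKBIA fell by 0.51, and CXCL8 (-0.84, adjusted p = 0.412) did not pass, though its adjusted p was 0.0464 without control 2. Enterocyte genes went both ways (7 up, 7 down of 32; adjusted p = 0.775), as did hypoxia-type (8 up, 6 down of 33), cell cycle (3 up, 2 down of 33), heat shock (5 up, 5 down of 20), NRF2 (7 up, 5 down of 26), interferon-response (2 up, 2 down of 28) and antimicrobial and mucin genes (5 up, 5 down of 21). Metallothionein and zinc carrier genes (4 up, 1 down of 10), junction proteins (1 up, 6 down of 25), uptake genes (5 up, 3 down of 37), apoptosis and p53 genes (2 up, 5 down of 22), microbe sensing (1 up, 1 down of 16), the M cell list (0 up, 2 down of 16) and goblet genes (2 up, 0 down of 9) did not pass as lists.

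B cell transcripts were higher on the bead arrays: 12 of 21 rose and 1 fell (12 and 2 over the list alone; camera adjusted p = 0.00133, and adjusted p = 0.652 with an estimated correlation), with a median of 1.16. HLA-DRA, an MHC class II chain, rose by 5.94 ± 1.07 (adjusted p = 0.000699) but was uneven, at 7.95, 6.10 and 10.78 on the 3 arrays, and its control mean of 2.34 lies below the array medians, so the size of the fold rests on a weak baseline, and CD48 rose by 2.87. In total, 3083 probe sets were higher and 3733 lower with beads than in controls, 209 and 465 of them by at least 2-fold, and 36.6% had arrays that did not overlap (10% by chance). Median centring, which moved the median by 0.102, gave 4042 higher and 2002 lower.

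**Figure D3:**
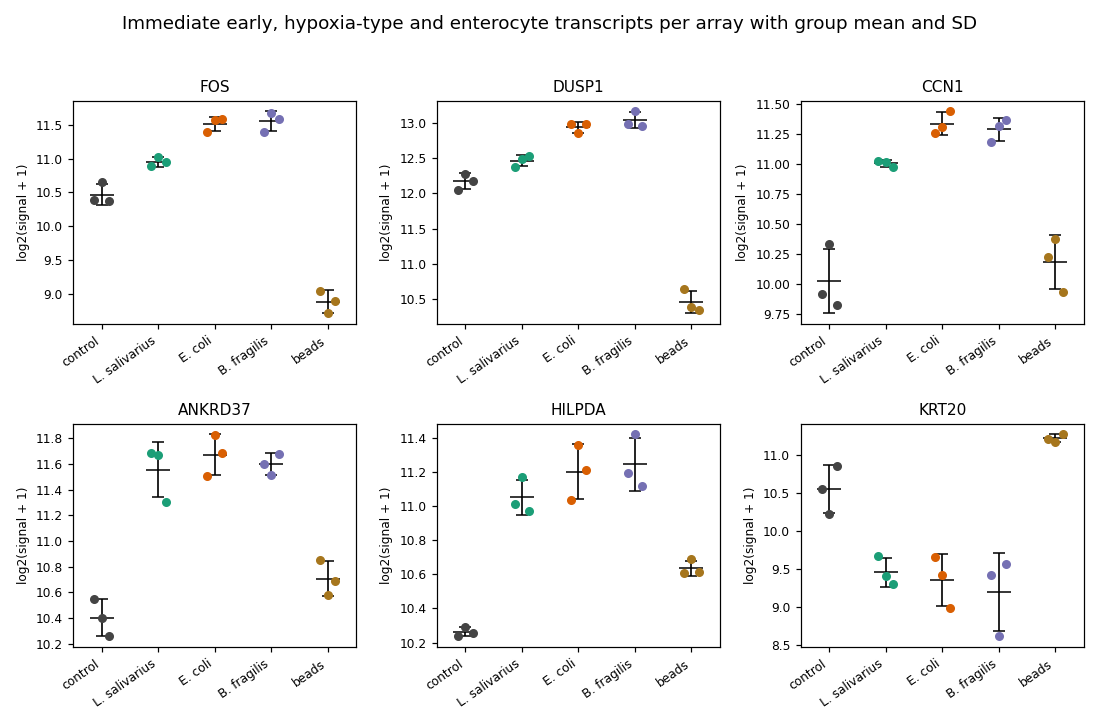
Immediate early (FOS, DUSP1, CCN1), hypoxia-type (ANKRD37, HILPDA) and enterocyte (KRT20) transcripts on each array. The vertical axes give log2(signal + 1); points are arrays, bars the group mean and SD of 3 arrays. Bead arrays lie lowest for FOS and DUSP1, 1.59 and 1.71 below the control mean. For ANKRD37 and HILPDA, arrays of each bacterium lie above all control arrays. Bead arrays also lie above all control arrays for these genes, but below every bacterial array.

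Set against beads, all 3 bacteria had higher immediate early mRNA, and E. coli and B. fragilis higher chemokine mRNA, although the labelling or hybridisation of bead arrays cannot be separated from these differences. CXCL8 was higher with E. coli by 4.96 and with B. fragilis by 5.68, CXCL1 by 3.13 and 3.43, while with L. salivarius CXCL8 (0.50), CXCL1 (0.28), CXCL3 (0.18) and CCL20 (-0.11) did not pass. FOS was higher by 2.07 with L. salivarius, 2.64 with E. coli and 2.68 with B. fragilis. DUSP1 was higher by 2.01, 2.48 and 2.58 in that order, and CYP4F12 by 3.50, 3.11 and 3.18. Immediate early genes numbered 27 higher and 0 lower of 35 with L. salivarius, 27 and 1 with E. coli, and 28 and 2 with B. fragilis (29 and 0, 28 and 1, and 30 and 2 over the list alone; adjusted p = 0.0241, 0.0104 and 0.0121 with an estimated correlation). NF-kB genes numbered 10 higher and 1 lower of 30, then 18 and 2, then 19 and 2 (11 and 2, 21 and 3, and 20 and 2 over the list alone; adjusted p = 0.525, 0.0760 and 0.0744 with an estimated correlation). B cell genes were lower in 5, 11 and 10 of 21; HLA-DRA was lower by -4.26, -6.24 and -4.40, and without bead array 3 its adjusted p was 0.0924 against L. salivarius and 0.0694 against B. fragilis. The totals were 3038 higher and 2784 lower for L. salivarius (1441 and 3901 after median centring), 3267 and 3142 for E. coli (2569 and 2847), and 3423 and 3524 for B. fragilis (3806 and 2411).

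The mean of the 3 bacteria was compared with the mean of control and beads; a difference here can come from the beads or from some of the species only. PTGS2 rose by 1.97 ± 0.19, NFKBIZ by 1.69, FOS by 1.67 ± 0.07, DUSP1 2.83-fold (adjusted p = 2.14e-11), the growth factor EREG by 1.41, the kinase MAP3K8 by 1.19, endothelin EDN1 by 1.16 and CCN1 by 1.11. KRT20 fell by 1.55 ± 0.13, the mitochondrial ATP synthase subunit ATP5F1C by 1.14, the subunit POLR1C of RNA polymerases by 0.81 and the membrane protein TM4SF20 by 0.79. Of 35 immediate early genes, 27 rose and 1 fell (29 and 1 over the list alone), and of 30 NF-kB genes 17 rose and 2 fell (20 and 3). Of 33 cell cycle genes 20 rose and none fell (23 and 0), of 33 hypoxia-type genes 17 rose and 4 fell (18 and 4), and of 32 enterocyte genes 2 rose and 10 fell (3 and 12). Camera called all 5 of these lists; with an estimated correlation the immediate early list passed (adjusted p = 0.0187), and the NF-kB, cell cycle, hypoxia-type and enterocyte lists did not (adjusted p = 0.128, 0.315, 0.315 and 0.317). In total, 3429 probe sets were higher and 3836 lower (3665 and 2810 after median centring). When the control alone was the reference and bead arrays were left out, 1641 were higher and 2584 lower, and 2726 probe sets were called in both. HLA-DRA was -2.00 against control and beads (adjusted p = 0.0437), a call that ended without any 1 of 9 arrays, with the highest adjusted p, 0.193, without bead array 3. Against the control alone HLA-DRA was 0.97 (adjusted p = 0.619) and DDIT4, 0.43 against control and beads, was -0.12 (adjusted p = 0.215), so neither passed there. Against the control alone FOS was higher by 0.87, EREG by 0.85 and NFKBIZ by 1.54, and DUSP1 1.56-fold. Of these 4 genes, only FOS passed with L. salivarius against the control.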

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

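The tests of the ACTB 3'/5' ratio, of dilution by Raji RNA, of separate processing of the bead arrays and of more Raji RNA with E. coli and B. fragilis were chosen after the results were seen; the tests of signal level, of poly-A controls and of other splits of the arrays were fixed before.

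Hybridisation and poly-A control probe sets, which the comparisons do not use, gave a signal in bead arrays above that of the untreated arrays. Hybridisation controls, which are added after labelling, were higher by 0.53 log2 units on bead than on control arrays. Poly-A controls, which are added to the RNA before labelling, were higher by 0.73. Signals for 18S ribosomal RNA went the other way, with a log2 difference of -2.79.

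Probe sets without a gene symbol made up 14.4% of those tested but 30.8% of the falls with E. coli, 31.9% with B. fragilis, 37.7% with L. salivarius and 15.6% with beads, while additional probe sets of named genes, 38.6% of those tested, gave 36.7% with E. coli and 39.6% with B. fragilis. A low signal level is argued against in both, since at matched signal the median for probe sets without a symbol lay below that for the others by -0.20 (95% interval -0.22 to -0.18) with E. coli and by -0.21 (-0.23 to -0.19) with B. fragilis, close to the unmatched -0.19 and -0.23. A stronger 3' bias of the labelled RNA stays open for both: with E. coli the mean ACTB 3'/5' ratio differed from the controls by -0.0549, within the control SD of 0.122, and with B. fragilis the ACTB ratio was higher by 0.272 and the GAPDH ratio was not (0.908 against 0.910 in controls). A biological loss of such transcripts, such as unspliced or alternatively ended RNA, remains an untested hypothesis.

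Immediate early genes were lower on bead than on control arrays, with a median of -0.53 over the list. Dilution of epithelial RNA by RNA of Raji cells, whose marker HLA-DRA was raised, would lower enterocyte genes by as much, and their median was -0.0539 (95% interval -0.17 to 0.14), which argues against it. Separate labelling or hybridisation cannot be told apart from the beads, since all bead arrays had hybridisation controls higher by 0.53 and no array of another group shared this. A real effect of beads, or of handling that differed between the groups, stays open.

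Chemokine and NF-kB genes were higher with E. coli and B. fragilis than with L. salivarius. L. salivarius 3 had higher poly-A controls than the other bacterial arrays. Without that array 7 of 8 such genes stayed higher with E. coli and 8 of 9 with B. fragilis, and the smaller share was 87.5%. The calls therefore did not rest on that array alone. These genes were chosen by their calls on the same arrays. Poly-A controls of L. salivarius 1 (8.64) also stayed above those of every E. coli and B. fragilis array. The test therefore cannot exclude a difference in poly-A controls. More RNA from Raji cells would raise B cell genes with E. coli and B. fragilis. The median of the B cell list was instead lower than with L. salivarius, at -0.44 with E. coli (95% interval -0.54 to -0.17) and -0.28 with B. fragilis. Over the 11 of 21 genes at or above the control median it was -0.0760 (-0.30 to 0.00734) and -0.17 (-0.42 to 0.0653). A slight rise is therefore not excluded. CCL20 was higher by 1.32 and 1.48, far above these intervals, which argues against more Raji RNA for rises of that size. Bacterial number and growth state, which are not given in the sources used here, and a response that depends on the bacterial species were not tested and stay open.

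With 10 splits for each pair of groups the share of splits cannot fall below 0.1, so the following are values only. The real split gave the most probe sets, as 1 of 10 splits, in the comparisons with the control: 295 against a highest other of 0 for L. salivarius, 2706 against 1 for E. coli, 3872 against 0 for B. fragilis and 6816 against 1 for beads. The same held, as 1 of 10, against beads for L. salivarius (5822 against 2), E. coli (6409 against 0) and B. fragilis (6947 against 1), and against L. salivarius for E. coli (45 against 1) and B. fragilis (150 against 1). For E. coli against B. fragilis all 10 splits reached the real count of 0, and the highest other gave 105, the source of which was not tested. For the 3 bacteria against control and beads, 1 of 100 drawn splits, the real one, gave 7265 and the highest other 22. For any difference among the 5 groups, 1 of 100 gave 9027 and the highest other 3459. Both argue against a chance split of the arrays, with 1 of 100 the smallest share that could be reached. These splits do not separate the treatments from the processing of the bead arrays.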

How the results depend on the processing

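The model without bead arrays and the comparison of 3 bacteria with the control alone were chosen after the data were seen, and the other alternatives beforehand. Of 677 named gene results, 661 passed the threshold and 165 of these lost their call in at least 1 model that left out 1 array. The call and direction held in 614 of 677 results with no level filter, 554 of 554 with the stricter filter, 676 of 677 with a pseudocount of 16, 644 with quantile normalisation, 609 with median centring, 579 without the variance trend and 549 of 590 with only the arrays compared. They held in 225 of 234 results in the model without bead arrays, but in only 54 of 87 for the 3 bacteria against the control alone, where 26 lost their call and 7 changed sign. Weak signal limits the folds of genes near or below the array median, and 3 arrays per group limit all of them. The cause of the changes listed here was not tested.

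The counts of probe sets moved by over 1.5 times as follows: with no level filter to 143 for L. salivarius against control and 72 for B. fragilis against L. salivarius; with median centring to 5841 for B. fragilis against control and 358 for B. fragilis against L. salivarius; without the variance trend to 67 for L. salivarius against control and 64 for B. fragilis against L. salivarius; with only the arrays compared to 344 for B. fragilis against L. salivarius; and against the control alone to 4225 for the 3 bacteria. Signs turned for HSPD1 (B. fragilis against beads) to 0.00876 with quantile normalisation, for TLR2 (B. fragilis against control) to 0.0359 with median centring, and for the 3 bacteria against the control alone to 0.00629 for AGR2, 0.0328 for BID, 0.16 for CD48, -0.12 for DDIT4, -0.0228 for DHCR7, 0.97 for HLA-DRA and -0.19 for TFF2.

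Leaving out each array in turn gave 35 to 289 probe sets for L. salivarius against control, 1195 to 2590 for E. coli, 1842 to 3951 for B. fragilis and 5076 to 5869 for beads; 4081 to 5181, 4702 to 5692 and 5002 to 6252 for L. salivarius, E. coli and B. fragilis against beads; 20 to 50 for E. coli and 39 to 82 for B. fragilis against L. salivarius; 0 to 1 for E. coli against B. fragilis; 5672 to 7131 for the 3 bacteria; and 7176 to 9349 for any group. With L. salivarius, CXCL8 ranged from -1.25 to 0.26, SPIB from -0.42 to 0.0152 and TNFAIP3 from -0.0404 to 0.13.

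Among the lists reported closely, camera with an estimated correlation ended 12 calls in comparisons of single groups with the control, and 4 of 5 for the 3 bacteria (NF-kB, cell cycle, hypoxia and enterocyte). Its adjusted p was 0.175 for hypoxia and 0.434 for cell cycle with L. salivarius. With E. coli it was 0.183 for the immediate early and NF-kB lists and 0.269 for the enterocyte, hypoxia and cell cycle lists. With B. fragilis it was 0.174 for the immediate early, NF-kB and enterocyte lists, 0.290 for hypoxia and 0.253 for cell cycle. It was the highest adjusted p among the alternatives of each of these, and the lowest ran from 3.72e-10 (cell cycle, B. fragilis) to 0.000837 (hypoxia, B. fragilis). With fry, cell cycle with L. salivarius (0.129) and enterocyte with E. coli (0.0585) did not pass. The enterocyte list with L. salivarius passed with quantile normalisation (0.0253) and with the mean of all probe sets of a gene (0.0127), over a range of alternatives of 0.0127 to 0.737. With beads, quantile normalisation made the NF-kB (0.0362) and enterocyte lists (0.0139) pass, and turned the hypoxia list to lower (0.0139), with ranges up to 0.652, 0.946 and 0.964.

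Arrays of different groups that carry the same replicate number did not deviate together, with correlations of -0.127 to 0.117 and 1 of 30 pairs above 0.1, and 5 of 15 arrays were closest to an array of their own number, so the numbers do not pair the arrays. With the replicate block, 89 probe sets were higher and 185 lower for L. salivarius, 885 and 1685 for E. coli, 1363 and 2363 for B. fragilis and 2971 and 3601 for beads, each against the control. The block made the NF-kB list pass with beads (adjusted p = 0.0382) and ended the calls of 25 of 677 named gene results; it changed no other call of a closely reported list and moved no count by over 1.5 times.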

Other observations

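The tests in this part were fixed beforehand, but the genes shown were picked from the named genes after their values were seen.

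Single genes of EGF receptor signalling rose, although their list did not pass (3 up, 1 down of 21 with E. coli, adjusted p = 0.687; 4 up, 3 down with B. fragilis, adjusted p = 0.727). EREG, the ligand epiregulin of the EGF receptor, rose by 0.98 ± 0.19 with E. coli and 0.96 ± 0.19 with B. fragilis, and HBEGF by 0.84 ± 0.13 and 0.85 ± 0.13, though the 1 other EREG probe set did not pass, and 1 of 2 others of HBEGF did. ERRFI1, a feedback inhibitor of the receptor, rose by 0.59 and 0.67 (limma, 3 arrays per group). With L. salivarius, EREG (0.60), HBEGF (0.44) and ERRFI1 (0.44) went the same way but did not pass. On bead arrays EREG and HBEGF fell by 1.13 and 0.73. GADD45A, a stress-induced growth arrest gene, rose by 0.73 with E. coli and 0.69 with B. fragilis, and BCL2L11, which encodes the pro-apoptotic BIM, by 0.49 and 0.66, though none of the 6 other BCL2L11 probe sets passed.

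MARVELD3 and PI3 moved with E. coli, B. fragilis and beads alike. MARVELD3, a tight junction protein, fell by 1.34 ± 0.17, 1.14 ± 0.17 and 0.98 ± 0.17, though of its 2 other probe sets none passed with the bacteria and 1 with beads. PI3, the protease inhibitor elafin, rose by 0.67, 0.93 and 0.83, and its 1 other probe set passed with B. fragilis and beads but not with E. coli. RAB5C, a regulator of early endosomes, did not move with beads (-0.07) and did not pass with L. salivarius (0.66), but rose by 0.87 ± 0.17 with E. coli and 1.06 ± 0.17 with B. fragilis, and 1 other RAB5C probe set passed the same way in each. The M cell list as a whole did not pass in any comparison, with adjusted p of 0.741, 0.687, 0.972 and 0.726 for L. salivarius, E. coli, B. fragilis and beads against the control.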
